A study of Rattus norvegicus with 14 samples.

How the data were processed

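RNA from left ventricular biopsies of 14 rats was hybridised to Affymetrix Rat230_2 arrays, with 1 array per rat, so that replicates are separate rats. Per the labels' protocols, total RNA was isolated with a PicoPure kit, amplified with the Affymetrix 2-cycle cDNA kit and labelled with biotin. The deposited values are intensity signals per probe set on a linear scale, made by the authors with MAS5, per the submitters' processing notes, which name it for 2 of the 14 samples. Detection calls and probe-level intensities were not used here. Means trimmed by 2% at each end lay between 500.161 and 500.189 on all arrays, within 1.00005-fold of each other, so no rescaling was needed. Correlations between arrays ran from 0.892 to 0.958.

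The value table held 31099 probe sets, of which 57 were Affymetrix controls and stayed out of the tests. Of the other 31042, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 had none; genes were named only from probe sets with 1 symbol. Of these, 20764 matched the GRCr8 gene table by Entrez ID, and 0 symbols changed. Neither the labels nor the file headers name a genome build for the array, so no coordinates are given. Every column of the table was mapped to a sample.

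Signals were tested as log2(signal + 16). The 18625 probe sets whose mean log2 signal lay above the 40th percentile were tested, which corresponds to a signal of 125, and they covered 10606 named genes. All 14 arrays entered 1 group-means model in limma 3.58.1 (lmFit, then eBayes with a trend; R 4.3.3), with 11 residual degrees of freedom. P values were two-sided and adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. Counts are counts of probe sets, and a fold change is on the log2(signal + 16) scale, which understates the change of dim genes. Log2 differences are given with their SE from limma and group levels with the SD over rats. Tables were read and plotted with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

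The comparisons were failure minus compensated, compensated minus SD and failure minus SD, and the mean of both Ren2 groups minus SD. The 36 gene lists, 21 of pathways and 15 of cell types that a ventricular biopsy may hold, had 696 entries, 625 of them named on the array. Each gene entered by its brightest probe set. Lists with at least 3 tested genes, 35 in all, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, whose directional test asks only whether a list's own genes move one way. The mean level of each list was also compared between groups by a two-sided exact permutation test, adjusted over the 35 lists of a comparison. The overlap of both comparisons against SD was set against 50 simulations of unchanged groups that share the controls, against independent sets of the same sizes and against splits of the 4 controls.

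The genes to be named were fixed by rule: per comparison the 10 largest rises and falls among passing probe sets with an established symbol (filled up to 5 per direction by the smallest p where fewer passed), 24 fixed genes, and up to 4 members of a list with the smallest p. The genes in the text are a selection from those the rule gives. Of the fixed genes 21 had a tested probe set; Ren, Spp1 and Ace had none. The groups, the limma and list tests, the lists, the naming rule and most alternatives were fixed before the data were examined; the exact permutation tests of list levels were added later.

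Per the file headers, the 10 Ren2 arrays shared run day 1 and 1 chip lot, and the 4 SD arrays were run on day 2 with chips of 2 other lots. Starts more than 30 minutes apart were counted as separate fluidics rounds, which gave 4: compensated rats 1 to 4 in round 1, compensated rats 5 and 6 and failure rats 7 and 8 in round 2, failure rats 9 and 10 in round 3 and the controls in round 4. Alternatives were a pseudocount of 1 or 64, quantile normalization, median centring, no filter or one at the 60th percentile, eBayes without a trend, array weights, 2-group fits, the mean of a gene's probe sets, rounds, modules or chip lots as blocks, covariates for the GAPDH 3'/5' ratio, the poly-A spike-in signal and the platelet and erythroid marker levels, and leaving out each rat in turn.

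The procedure was tested on simulated data with the real probe sets' levels and spread, independent errors and 66 or 67 changed probe sets per size of change. Changes of 1 log2 unit were recovered for 68.7% of changed probe sets in failure minus compensated, 70.1% in compensated minus SD and 55.2% in failure minus SD, and changes of 2 log2 units for 95.5%, 89.4% and 97.0%. Changes of 0.5 log2 units were recovered for only 8.96%, 11.9% and 10.4%. False calls made up 5.74%, 8.06% and 6.09% of calls. A shifted list was recovered by camera and fry, with 0 false calls among 33 other lists. In the real data other splits of the rats gave medians of 6.5 to 7 camera list calls, with up to 17, so that 0 does not describe camera's false calls in these data.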

Results

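Gene expression was measured in left ventricular biopsies of 14 male rats aged 10 weeks, with 1 array per rat. Of these, 10 were Ren2 rats, a Sprague Dawley line that carries the mouse renin gene Ren-2 and develops high blood pressure, and 4 were Sprague Dawley (SD) controls without high blood pressure. The strain field of the SD rats repeats the Ren2 strain and contradicts their titles; the titles were followed, and every comparison with SD rests on them. The labels divide the Ren2 rats into 6 called compensated and 4 called failure. The series title speaks of predicting heart failure, while the design text describes both Ren2 groups as hypertensive and without heart failure, so the words compensated and failure are used below as the names of the groups. Replicates are separate rats. The deposited MAS5 signals had trimmed means between 500.161 and 500.189 on every array, and 18625 probe sets were bright enough to be tested. The number of arrays limits the precision: a simulated change of 2-fold between the Ren2 groups was recovered for 68.7% of changed probe sets, one of 4-fold for 95.5% and one of 0.5 log2 units for only 8.96%. These shares hold for independent errors and for 66 or 67 planted changes per size, and do not give the recovery in the real comparison. There Alas2, for example, differed by more than 4-fold (−2.09 on the log2 scale) and did not pass.

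The first question was what separates the failure group from the compensated group at this age. Markers of blood cells showed the widest gap, and they were lower in the failure group. The 7 platelet genes had a median log2 difference of −1.59, and the 6 erythroid genes one of −1.80. Pf4, a chemokine stored in platelet granules, had a log2 signal of 14.17 ± 0.57 (SD, n = 6) in compensated and 12.58 ± 0.86 (SD, n = 4) in failure ventricles. Alas2, the first enzyme of haem synthesis in red cell precursors, was at 13.91 ± 0.78 and 11.82 ± 1.09. Macrophage and fibroblast markers had medians of −0.37 and −0.59, most of which rested on failure rat 9, since without it the medians were −0.06 and −0.07. Genes of cardiac hypertrophy did not separate the groups, with a median of −0.02.

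No platelet or erythroid gene passed the limma test over all probe sets, but adjusted over the list alone all 7 platelet genes and all 6 erythroid genes fell. The log2 differences were −1.59 ± 0.32 (SE) for Pf4, −1.59 ± 0.32 for the platelet integrin Itga2b, −1.70 ± 0.35 for Treml1, a receptor of platelet granules, and −1.49 ± 0.29 for F13a1, the clotting factor XIII subunit. They were −2.09 ± 0.44 for Alas2, −0.99 ± 0.22 for Hbb, a beta globin, −1.83 ± 0.41 for Bpgm, which makes the red cell metabolite 2,3-bisphosphoglycerate, and −1.69 ± 0.39 for Slc4a1, the red cell anion exchanger. With limma and all probe sets these genes had adjusted p values between 0.0937 and 0.108. Camera gave adjusted p = 4.86e-10 for the platelet list and 7.45e-09 for the erythroid list, but adjusted p = 0.271 for each with an estimated correlation. The mean level of the platelet list differed by −1.49 with an exact permutation p = 0.0143 and that of the erythroid list by −1.74 with the same p, which became 0.25 after adjustment over 35 lists. The smallest p that 6 against 4 rats allow is 0.00476. Within the single fluidics round that held rats of both Ren2 groups, 2 of each, the median platelet difference was −1.14 and the erythroid one −2.23. The compensated rats of that round, rats 5 and 6, had platelet marker levels of −0.19 and 0.34 relative to the mean of all arrays, against 1.04 to 1.83 in compensated rats 1 to 4 and −1.03 to 0.16 in the failure rats.

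**Figure D1:**
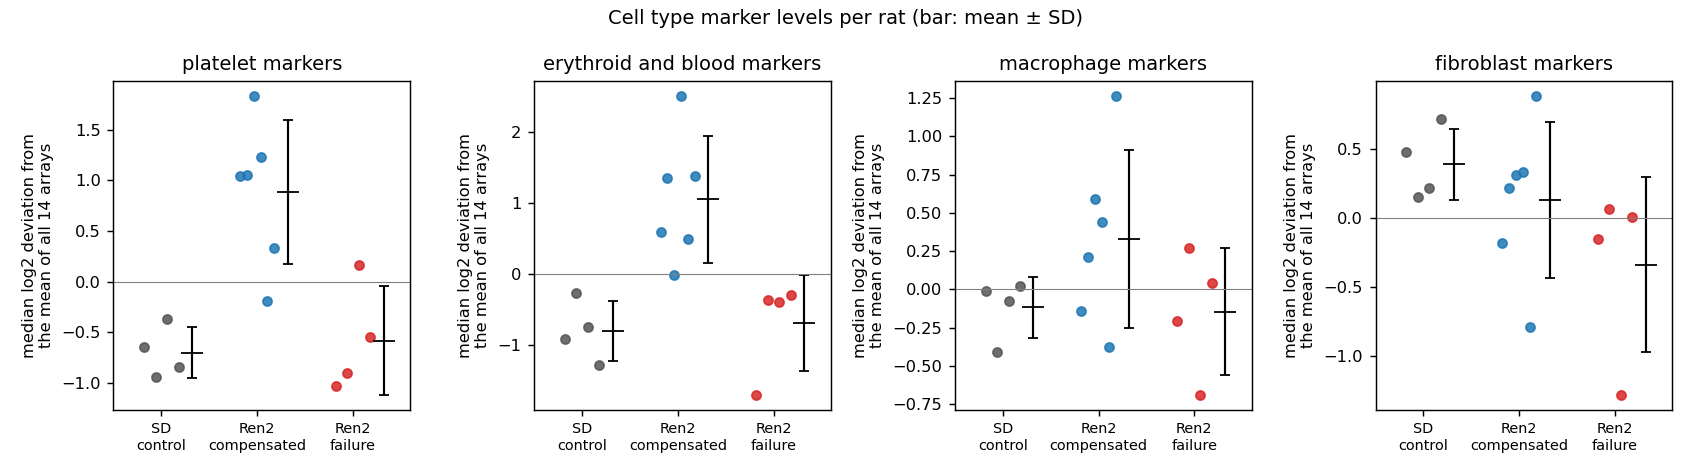
Marker levels of 4 cell types in each rat: each point is 1 rat, the y axis is the median log2 deviation of the list's genes from their mean over all 14 arrays, and bars give the group mean ± SD. Platelet and erythroid levels of the failure rats overlap those of the SD controls and lie mostly below those of the compensated rats, and failure rat 9 has the lowest fibroblast level, −1.28.

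Markers of several other cell types also had medians below 0. All 13 macrophage genes were lower in the failure group, and 2 of them fell when adjusted over the list alone (camera adjusted p = 0.00226, adjusted p = 0.6253 with an estimated correlation). Fcer1g, a signalling chain of Fc receptors, differed by −1.36 ± 0.26 (SE) and Cd68, a lysosomal protein of macrophages, by −1.43 ± 0.32. The neutrophil list kept only 2 tested genes and was not given a list test; S100a9, an abundant neutrophil protein, was lower by −2.07 ± 0.57. Of 35 extracellular matrix genes, 31 were lower (median −0.37, camera adjusted p = 0.000696, adjusted p = 0.649 with an estimated correlation), and 1 fell when adjusted over the list alone. Bgn, the proteoglycan biglycan, differed by −0.78 ± 0.19, Lox, which cross-links collagen, by −1.07 ± 0.40 and Col1a1, a chain of type I collagen, by −0.63 ± 0.23. Both this list and the fibroblast list (11 of 12 genes lower, camera adjusted p = 0.0263, adjusted p = 0.649 with an estimated correlation) lost their calls without failure rat 9, with medians of −0.09 (camera adjusted p = 0.378) and −0.07 (0.677). Among the endothelial genes 11 of 12 were lower (median −0.21, camera adjusted p = 0.0174, adjusted p = 0.6253 with an estimated correlation), with Cldn5, a tight junction protein, at −0.87 ± 0.29. The interferon list (median −0.17) and the inflammatory cytokine list (median −0.30) each had a camera adjusted p = 0.0263, which became 0.649 and 0.6253 with an estimated correlation. Rsad2, an antiviral protein induced by interferon, had a log2 signal of 13.27 ± 0.85 (SD, n = 6) in compensated and 11.27 ± 1.09 (SD, n = 4) in failure rats, and the chemokine Ccl5 differed by −1.55 ± 0.39 (SE); neither passed over all probe sets. Without failure rat 9 the medians were −0.17 for endothelial genes (camera adjusted p = 0.0609), −0.10 for interferon (0.231), −0.27 for inflammatory (0.0609) and −0.06 for macrophage genes (0.098). Without compensated rat 6 the camera adjusted p values were 0.0872 (endothelial), 0.147 (interferon), 0.111 (inflammatory) and 0.111 (fibroblast). Without compensated rat 3 they were 0.0628 (interferon), 0.0628 (inflammatory) and 0.0732 (fibroblast), and without failure rat 7 one of 0.0587 (interferon). With the fluidics round as a block, which rests on round 2 because rounds 1 and 3 each held 1 Ren2 group, the matrix (median −0.08, camera adjusted p = 0.637), fibroblast (−0.0024, 0.992), macrophage (−0.20, 0.126) and interferon (−0.16, 0.153) calls ended. The endothelial (−0.42, 0.0145) and inflammatory (−0.39, 0.0275) lists passed. With the GAPDH 3'/5' ratio as a covariate, which differs between the Ren2 groups, neither did: the medians were −0.13 for endothelial (camera adjusted p = 0.534) and −0.28 for inflammatory genes (0.369). The interferon (−0.12, 0.178), matrix (−0.33, 0.0688) and fibroblast (−0.68, 0.0727) calls ended as well, while the macrophage list passed (−0.53, 0.0114). With the platelet and erythroid marker levels as covariates, chosen after the data were seen, the interferon median was 0.02 (camera adjusted p = 0.874) and the inflammatory one 0.05 (0.842). The macrophage (−0.15, 0.547), endothelial (−0.23, 0.0986) and fibroblast (−0.64, 0.0986) calls ended too, and the matrix list passed (median −0.61). The mean platelet and erythroid levels themselves differed by −1.49 and −1.74 between the Ren2 groups. The loss of calls therefore does not show that blood accounts for these shifts.

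One probe set passed over all probe sets. It belonged to Dgkd, a diacylglycerol kinase, and fell by 1.90 ± 0.23 (SE) on the log2 scale in the failure group (limma adjusted p = 0.00568). The other Dgkd probe sets differed by −0.38 and −0.40, and neither passed. At an adjusted p under 0.1 there were 50 probe sets, 43 of them lower. At an unadjusted p under 0.05 there were 2230, where 931 would be expected on average without any change. Probe sets that move together widen the spread of this count, and it was not scored for other splits of the rats. The excess therefore does not show a difference between the groups. The probe sets next in line after Dgkd did not pass: among the lower ones were those of Nfe2, a transcription factor of red cell and platelet precursors (−2.25 ± 0.36, limma adjusted p = 0.0875), F5, the clotting factor V (−1.53 ± 0.27), Tmod2 and Mylk2. Among the higher ones, also not passing, were Mrpl37 of the mitochondrial ribosome (1.26 ± 0.21, limma adjusted p = 0.0875), Mcur1, a regulator of mitochondrial calcium uptake (0.60 ± 0.11), Phospho1, Emc6 and Vangl1.

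None of the heart failure genes fixed beforehand passed between the Ren2 groups. Nppa and Nppb, which encode the atrial and B-type natriuretic peptides, differed by −0.16 ± 0.33 (SE) and 0.11 ± 0.14. Nppa lay near the top of the scale in both groups, at log2 signals of 15.10 and 14.94, so its small difference does not show that its RNA level was alike. Myh7, the slow beta myosin heavy chain, differed by −0.23 ± 0.08 (limma adjusted p = 0.261). Scarb2, a lysosomal membrane protein, differed by 0.16 ± 0.14 (limma adjusted p = 0.681) and Thbs2, the matrix protein thrombospondin 2, by −0.31 ± 0.34 (limma adjusted p = 0.752). Vcl, the adhesion protein vinculin, was the 1 gene of the intercalated disc list to rise when adjusted over the list alone, by 0.31 ± 0.09, but its other probe sets stood at 0.18 and −0.06, and its list had a median of 0.10 (camera adjusted p = 0.131). The sarcomere list had a median of −0.09 (camera adjusted p = 0.0485, adjusted p = 0.754 with an estimated correlation), and its median was 0.04 with quantile normalization; Tpm1, a tropomyosin, stood at −0.25 ± 0.08. Immediate early genes (median −0.28, 18 of 22 lower), lymphocyte markers (median −0.28, 7 of 8 lower) and genes of the ubiquitin-proteasome system (median 0.16, 11 of 16 higher) had camera adjusted p values of 0.0263, 0.0263 and 0.049, and with an estimated correlation adjusted p values of 0.649, 0.6253 and 0.6253. With the fluidics round as a block none of these lists passed: the medians were −0.11 for immediate early genes (camera adjusted p = 0.881), −0.39 for lymphocytes (0.0902), 0.17 for ubiquitin-proteasome (0.329) and −0.0181 for the sarcomere (0.992). With the GAPDH ratio as a covariate the lymphocyte median was −0.05 (camera adjusted p = 0.758) and the ubiquitin-proteasome one −0.0339 (0.573), while the immediate early (−0.38, 0.0141) and sarcomere (−0.15, 0.000138) lists passed. With the blood marker levels as covariates the immediate early median was 0.26 (0.256), the lymphocyte one 0.18 (0.168) and the ubiquitin-proteasome one −0.0458 (0.874). Because these levels differ between the Ren2 groups, this does not show that blood accounts for the list shifts. Leaving out 1 rat ended the sarcomere, immediate early, lymphocyte and ubiquitin-proteasome calls as well, with camera adjusted p values of up to 0.232 (without compensated rat 5), 0.146 (without failure rat 8), 0.117 (without compensated rat 4) and 0.105 (without failure rat 8). Camera called 12 of 35 lists in this comparison, none was called with an estimated correlation or by fry, and 1 Dgkd probe set passed by limma, a count that became 84 without compensated rat 5, 17 without failure rat 9, 2 without compensated rat 3, failure rat 8 or failure rat 10, and 0 with the fluidics round as a block or the GAPDH 3'/5' ratio as a covariate. With the blood marker levels as covariates the Dgkd probe set no longer passed, and 1 other probe set passed, which was higher.

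The second question was how the ventricle of the compensated Ren2 rats differed from that of SD controls. Of the hypertrophy and fetal genes 11 of 16 rose, of the sarcomere genes 11 of 20 and of the heat shock genes 6 of 14, while 10 of 26 fatty acid oxidation genes fell. None of these list calls held with an estimated correlation (adjusted p = 0.149, 0.647, 0.067 and 0.889). The sarcomere median was 0.03 with quantile normalization, and the fatty acid oxidation median turned from −0.39 to 0.29 with the GAPDH 3'/5' ratio as a covariate. Nppa rose from a log2 signal of 10.39 ± 1.18 (SD, n = 4) to 15.10 ± 0.10 (SD, n = 6), near the top of the scale, so that the measured 26.3-fold may understate its rise. Nppb rose 1.85-fold, Myh7 1.85-fold and Hspb1, a small heat shock protein, 3.01-fold. Decr1, an auxiliary enzyme of unsaturated fatty acid oxidation, fell to a log2 signal of 12.04 ± 0.49 from 13.09 ± 0.10. Platelet and erythroid markers were also higher, with medians of 1.49 and 1.95.

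Of the 16 hypertrophy and fetal genes, 11 rose, none fell and 5 did not pass; adjusted over the list alone 12 rose (median 0.58, camera adjusted p = 1.15e-07, adjusted p = 0.149 with an estimated correlation). In log2 units the rises were 4.72 ± 0.33 (SE) for Nppa, 0.89 ± 0.14 for Nppb, 0.89 ± 0.08 for Myh7, 1.34 ± 0.19 for Enah, an actin regulator, 0.63 ± 0.09 for the muscle LIM protein Csrp3, 0.49 ± 0.08 for skeletal actin Acta1, 0.46 ± 0.07 for Ankrd1, a stretch-responsive protein of the sarcomere, and 1.61 ± 0.31 for Ccn2, a connective tissue growth factor. Nppa stood at a mean signal of 35283 in compensated rats, near the mean of the highest signal on their arrays, 42343, so its size is measured close to the top of the scale. Of the 20 sarcomere genes, 11 rose and 1 fell, and adjusted over the list alone 13 rose and 1 fell (median 0.32, camera adjusted p = 0.000156, adjusted p = 0.647 with an estimated correlation). Tpm1 rose by 0.51 ± 0.08, the chaperone Cryab by 0.45 ± 0.08, troponin T Tnnt2 by 0.41 ± 0.08 and alpha myosin Myh6 by 0.40 ± 0.09. Another Tpm1 probe set fell by 1.06 while the rising ones averaged 0.46, so the direction of this gene depends on the probe set. With quantile normalization the sarcomere median was 0.03 (camera adjusted p = 0.965), and Acta1, Ankrd1, Tpm1, Cryab, Tnnt2 and Myh6 no longer passed. Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose by 0.43 ± 0.07 and it too did not pass with quantile normalization. The highest signal on an array averaged 31702 in SD and 42343 in compensated rats, so the bright end of the scale differed between the groups. Rises of this size in bright genes cannot be told apart from that difference. In the heat shock list 6 of 14 genes rose, or 7 adjusted over the list alone, and none fell (median 0.34, camera adjusted p = 0.000237, adjusted p = 0.067 with an estimated correlation). Hspb1 rose by 1.59 ± 0.15, Hspb7, a small heat shock protein of heart muscle, by 1.07 ± 0.09 and the co-chaperone Hsph1 by 0.93 ± 0.11.

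**Figure D2:**
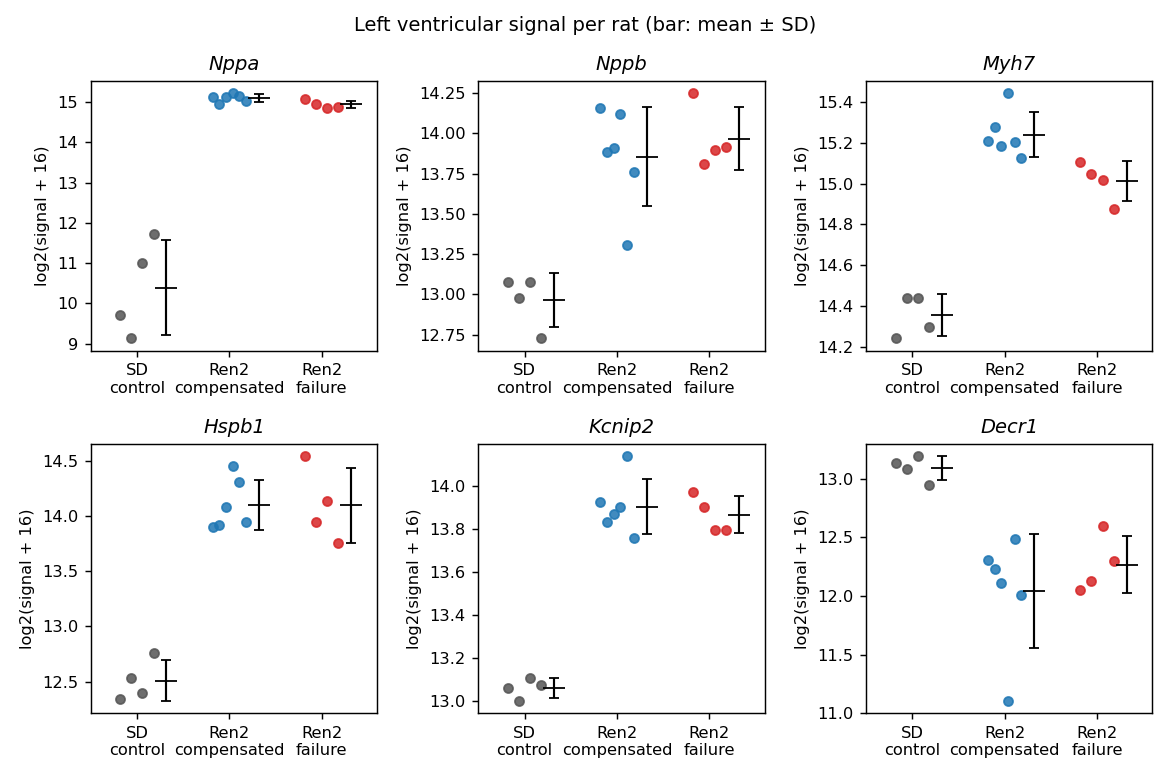
Log2(signal + 16) of 6 genes in each rat: each point is 1 rat, and bars give the group mean ± SD (n = 4 SD control, 6 compensated, 4 failure; each panel has its own y axis). Nppa, Nppb, Myh7, Hspb1 and Kcnip2 lie above all SD controls in every Ren2 rat, and Decr1 lies below them.

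Of 26 fatty acid oxidation genes, 10 fell and 1 rose, and adjusted over the list alone 14 fell and 2 rose (median −0.39, camera adjusted p = 0.000153, adjusted p = 0.889 with an estimated correlation). Decr1 fell by 1.05 ± 0.20 (SE), Acadvl, the very long chain acyl-CoA dehydrogenase, by 0.95 ± 0.18, Hadha, a subunit of the trifunctional protein, by 0.99 ± 0.21 and the thioesterase Acot2 by 1.17 ± 0.26. A second Hadha probe set rose by 0.51, so the direction of this gene depends on the probe set. The log2 ratio of 3' to 5' signal of the GAPDH control, a measure of RNA length after amplification, was 1.63 ± 0.24 (SD, n = 6) in compensated rats, 1.17 ± 0.15 (SD, n = 4) in failure rats and 0.92 ± 0.21 (SD, n = 4) in SD controls, and the list's level fell with it within groups, by 0.91 per unit (95% interval −1.53 to −0.29, permutation p = 0.00905). With this ratio as a covariate the list's median was 0.29 (camera adjusted p = 0.0353) in place of −0.39. With the platelet and erythroid marker levels as covariates it was −0.25 (0.0937), and both sets of covariates were chosen after the data were seen. Of 18 glycolysis genes, 6 rose and none fell, while adjusted over the list alone 6 rose and 1 fell (median 0.24, camera adjusted p = 0.021, adjusted p = 0.622 with an estimated correlation; median −0.01 with quantile normalization). Eno1, the widely expressed enolase, rose by 0.89 ± 0.10, Aldoa, an aldolase, by 0.50 ± 0.08 and Pgam1, a phosphoglycerate mutase, by 0.51 ± 0.08. Without SD rat 14 the glycolysis list had a camera adjusted p = 0.0982.

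**Figure D3:**
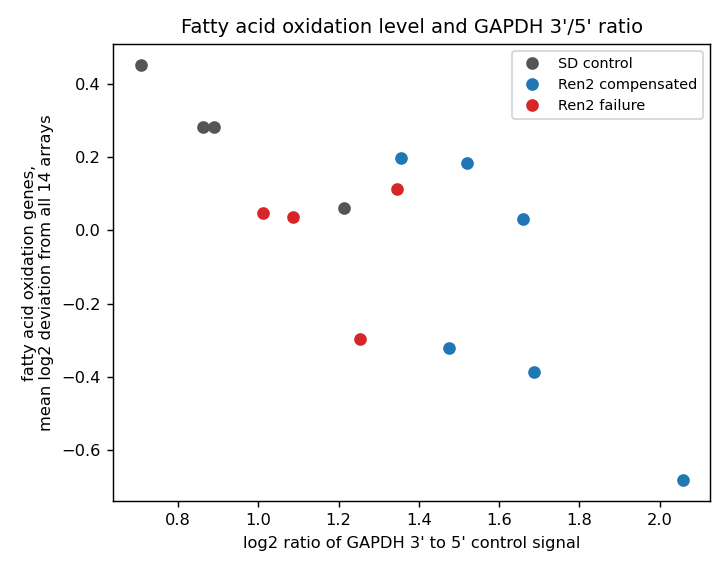
Mean level of the fatty acid oxidation genes (y axis, log2 deviation from the mean of all 14 arrays) against the log2 GAPDH 3'/5' ratio (x axis) in each rat, coloured by group. Compensated rat 4 has the highest ratio, 2.06, and the lowest level, −0.68; the SD control with the lowest ratio, 0.71, has the highest level, 0.45.

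Matrix genes rose in part: of 35, 6 rose and none fell, adjusted over the list alone as well (median 0.14, camera adjusted p = 0.383). Tgfb2, a growth factor of the TGF-beta family, rose by 2.68 ± 0.36 (SE), Bgn by 1.37 ± 0.19, fibronectin Fn1 by 1.17 ± 0.23 and Col4a1, a basement membrane collagen, by 0.60 ± 0.14. The fibrillar collagens Col1a1 (0.15 ± 0.23) and Col3a1 (−0.30 ± 0.38) did not pass. Of the platelet list 6 of 7 genes rose, and 6 adjusted over the list alone (camera adjusted p = 0.000153, adjusted p = 0.592 with an estimated correlation). In the erythroid list 5 of 6 rose, and 6 adjusted over the list alone (camera adjusted p = 0.00164, adjusted p = 0.622 with an estimated correlation), and with the GAPDH ratio as a covariate its median was 1.15 (camera adjusted p = 0.0566). Pf4 rose by 2.15 ± 0.32, Treml1 by 2.22 ± 0.35, Alas2 by 2.15 ± 0.44 and Bpgm by 2.07 ± 0.41. The largest rises in this comparison also included Nfe2 at 2.69 ± 0.36 and Plek, a substrate of protein kinase C in platelets, at 2.95 ± 0.54.

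In all, 1993 probe sets rose and 1674 fell by limma, of which 521 and 383 differed by at least 2-fold. Median centring of the arrays turned this split into 1191 higher and 2304 lower, and it moved the median of all tested probe sets from 0.05 to −0.07. The largest rises were those of Sbsn, a secreted protein of epithelia, at 5.22 ± 0.42 (SE, limma adjusted p = 1.03e-06), Nppa, Nrgn, a calmodulin-binding protein, at 3.72 ± 0.54, Kcne1, a potassium channel subunit, at 3.27 ± 0.64, Bex1 at 2.97 ± 0.17, Plek, Barhl2, Akip1 at 2.80 ± 0.25, Nfe2 and Cpeb1. The largest falls were those of Rab14, a small GTPase of endosomes, at −4.61 ± 0.49, Kif13a at −4.03 ± 0.59, Ano5, Rdx, Fam111a, RT1-Db1, a class II antigen chain, at −2.53 ± 0.43, Slpi, a protease inhibitor, at −2.53 ± 0.26, Prodh, Tsc22d4 and Rfx4, of which the Fam111a call was ended by 14 alternatives and the Rfx4 call by 17. The Rab14 fall belonged to 1 of its 4 probe sets, and another one rose by 0.70. Every Ren2 array ran on the first run day and chip lot and every SD array on the second run day, so strain cannot be told apart from run day. With the GAPDH ratio as a covariate 116 probe sets passed, 107 of them among the 3667. The SE of a probe set grew by a median of 1.85-fold, and called changes kept a median of 0.802 of their size. Of 61 passing genes named for this comparison, 47 no longer passed then and 46 no longer passed with platelet and erythroid levels as covariates, while Sbsn, Nppa, Bex1, Akip1, Myh7, Eno1, Hspb7, Hspb1 and Kcnip2 passed under every alternative run. The marker genes Pf4, Treml1, Alas2 and Bpgm were not part of the fit with these levels. The mean platelet and erythroid levels themselves differed by 1.67 and 1.74 between these groups, so this loss of calls does not show that blood accounts for the changes.

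The third question was how the failure rats differed from SD controls. Of the hypertrophy and fetal genes 10 of 16 rose, a list call with adjusted p = 0.117 with an estimated correlation, and of the heat shock genes 7 of 14 rose, with adjusted p = 0.0286 with an estimated correlation. Nppa rose to a log2 signal of 14.94 ± 0.10 (SD, n = 4) from 10.39 ± 1.18 (SD, n = 4), again near the top of the scale, so that the measured 23.5-fold may understate its rise. Nppb rose 2.00-fold, Hspb1 3.01-fold and Gata4, a cardiac transcription factor, 2.05-fold. RT1-Bb, a class II antigen chain, fell to a log2 signal of 6.61 ± 0.51 from 9.05 ± 0.28. Platelet and erythroid markers stood near the control level, with medians of 0.08 and −0.10, and Pf4 differed by 0.56 ± 0.35 (SE, limma adjusted p = 0.348).

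Of the 16 hypertrophy and fetal genes, 10 rose, none fell and 6 did not pass; adjusted over the list alone 12 rose and 1 fell (median 0.62, camera adjusted p = 2.39e-08, adjusted p = 0.117 with an estimated correlation). In log2 units Nppa rose by 4.56 ± 0.36 (SE), Nppb by 1.00 ± 0.16, Myh7 by 0.66 ± 0.09, Gata4 by 1.03 ± 0.15, Enah by 1.44 ± 0.21, Ccn2 by 1.67 ± 0.33 and Acta1 by 0.29 ± 0.08, a call that 15 alternatives ended. A second Myh7 probe set rose by 2.03 ± 0.27 here and by 1.79 ± 0.25 in the compensated group. The heat shock list was the only one called with an estimated correlation too: 7 of 14 genes rose and none fell, and adjusted over the list alone 8 rose and 1 fell (median 0.34, camera adjusted p = 5.35e-05, adjusted p = 0.0286 with an estimated correlation). Hspb1 rose by 1.59 ± 0.16, Hspb7 by 0.90 ± 0.10, Hsph1 by 1.03 ± 0.12 and the chaperone Hsp90ab1 by 0.79 ± 0.14. Of 20 sarcomere genes 4 rose and none fell, and adjusted over the list alone 9 rose and 2 fell (median 0.22, camera adjusted p = 0.00434, adjusted p = 0.95 with an estimated correlation; median 0.03 with quantile normalization). Des, the muscle filament protein desmin, rose by 0.64 ± 0.15, and Atp2a2 at 0.22 ± 0.08 did not pass (limma adjusted p = 0.0722). The highest signal on an array averaged 38722 in failure and 31702 in SD rats, so small rises of bright genes carry the same limit here.

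Of 26 fatty acid oxidation genes 2 fell and none rose, and 3 fell when adjusted over the list alone (median −0.27, camera adjusted p = 0.0052, adjusted p = 0.95 with an estimated correlation). Decr1 fell by 0.82 ± 0.22 (SE) and Eci1, an enoyl-CoA isomerase, by 0.60 ± 0.18, calls that 9 and 13 alternatives ended. Another Eci1 probe set stood at 0.73 (limma adjusted p = 0.157), and Hadha stood at −0.74 ± 0.23 (limma adjusted p = 0.0503). Fry, which was planned, did not call the list (adjusted p = 0.537). Its camera call also ended under 4 alternatives chosen after the data were seen: the GAPDH ratio as a covariate (median −0.05, camera adjusted p = 0.71), fluidics modules as a block (−0.09, 0.409), poly-A signals as a covariate (−0.20, 0.0506) and leaving out failure rats 7 and 9 (−0.17, 0.0524). Of 18 glycolysis genes 3 rose and none fell, adjusted over the list alone as well (median 0.21, camera adjusted p = 0.0052, adjusted p = 0.54 with an estimated correlation; median 0.07 with quantile normalization). Eno1 rose by 1.04 ± 0.11, Pgam1 by 0.60 ± 0.09 and Aldoa by 0.37 ± 0.08. Of 25 interferon and antigen presentation genes 23 were lower and 2 fell, and 1 fell when adjusted over the list alone (median −0.28, camera adjusted p = 0.0052, adjusted p = 0.95 with an estimated correlation). RT1-Bb fell by 2.44 ± 0.32, a call kept under every alternative run, and RT1-Da, another class II chain, by 1.44 ± 0.44, a call that 15 alternatives ended. Without failure rats 7 and 9, whose poly-A spike-in signals were the highest, the interferon list had a median of −0.09 (camera adjusted p = 0.341) and the fibroblast list one of −0.16 (0.473).

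Of the 12 fibroblast genes 1 fell over all probe sets, and 2 fell and 1 rose when adjusted over the list alone (median −0.93, camera adjusted p = 0.0248, adjusted p = 0.95 with an estimated correlation; adjusted p = 0.309 without failure rat 9 and 0.129 without SD rat 14). The list's call also ended without the filter on dim probe sets (camera adjusted p = 0.0849) and with fry (adjusted p = 0.512). With poly-A signals as a covariate it ended too (median −0.50, camera adjusted p = 0.198). Gsn, the actin-severing protein gelsolin, fell by 1.63 ± 0.37 (SE). Of 35 matrix genes 3 rose and 2 fell, adjusted over the list alone as well (median −0.14, camera adjusted p = 0.664): Tgfb2 rose by 2.67 ± 0.39 and Col4a1 by 0.66 ± 0.16, while Col6a1, a microfibrillar collagen, fell by 0.82 ± 0.23 and Lox by 1.48 ± 0.43. The immediate early gene Jun fell by 0.86 ± 0.25 and the phosphatase Dusp1 by 1.39 ± 0.25, Cd68 fell by 1.23 ± 0.35, and Txnip, an inhibitor of thioredoxin, fell by 1.58 ± 0.28. Of these falls, the calls of Lox, Col6a1, Cd68 and Jun were ended by 13, 11, 11 and 10 alternatives. Scarb2 stood at 0.44 ± 0.16 (limma adjusted p = 0.084) and Thbs2 at −0.07 ± 0.37.

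In all, 1058 probe sets rose and 927 fell, of which 271 and 320 differed by at least 2-fold. The largest rises were those of Sbsn at 4.84 ± 0.46 (SE, limma adjusted p = 8.49e-06), Nppa, Kcne1 at 3.61 ± 0.70, Bex1 at 3.33 ± 0.19, Akip1 at 3.25 ± 0.28, Cpeb1, Pea15, a death effector domain protein, at 2.77 ± 0.46, Tgfb2, Bdh1, the mitochondrial ketone body enzyme, at 2.64 ± 0.66 and Maoa, monoamine oxidase A, at 2.52 ± 0.34. The largest falls were those of Rfx4 at −3.96 ± 0.90, Rab14 at −3.85 ± 0.54, RT1-Db1 at −3.37 ± 0.47, Ano5, Fam111a, Sfswap, Rps6ka5, RT1-Bb, Abca8a and Slpi at −2.37 ± 0.29. The Fam111a means rested on spread among the controls (log2 10.16 ± 2.81, SD, n = 4), and its call was lost under 17 alternatives. The count of 1985 passing probe sets became 710 without failure rats 7 and 9 and 1303 without SD rat 12, and strain and run day cannot be told apart here either.

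**Figure D4:**
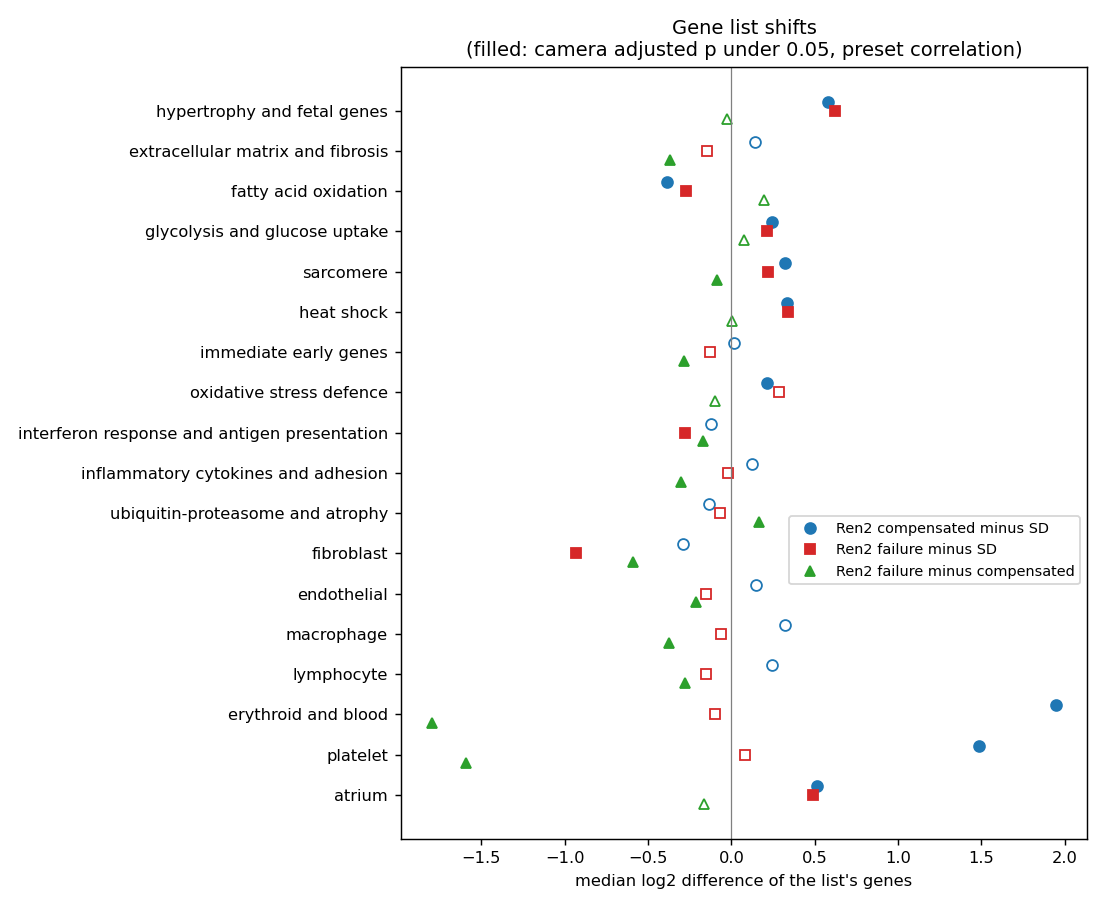
Median log2 difference (x axis) of the genes of each list called in at least 1 comparison (y axis), with circles for compensated minus SD, squares for failure minus SD and triangles for failure minus compensated; filled symbols passed camera with a preset correlation. The platelet and erythroid lists stand at 1.49 and 1.95 in compensated minus SD and at −1.59 and −1.80 in failure minus compensated.

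Both Ren2 groups differed from the controls in largely the same way. Every Ren2 array ran on the first run day and every SD array on the second, so an effect of the run would be shared as well. The independent sets, the simulation and the control splits below cannot tell such an effect from one of the strain. With Nppa, Bex1, Akip1, Hspb1 and Enah among them, 823 probe sets rose in both comparisons, and with Slpi, RT1-Bb, Nr3c2 and Dusp1 among them, 735 fell in both. Independent sets of these sizes would share 113 and 83.3, and 0 probe sets passed in both with opposite signs. The mean of both Ren2 groups differed from the controls in 3511 probe sets, 1890 higher and 1621 lower, and in 1234 higher and 1923 lower after median centring. Across probe sets, which are not independent replicates, the log2 changes of the comparisons correlated with r = 0.789, where unchanged groups that share these controls gave 0.548 on average in simulation; the covariance was 0.196 against a simulated 0.0335. With the 4 controls split between the comparisons, r ranged from 0.531 to 0.628, the covariance from 0.154 to 0.171, and 233 to 267 probe sets rose and 170 to 204 fell in both, with 1 opposite call in 2 of the 6 splits. The shared count of 1558 became 110 with the GAPDH ratio as a covariate, 647 without failure rats 7 and 9 and 1030 without SD rat 12.

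**Figure D5:**
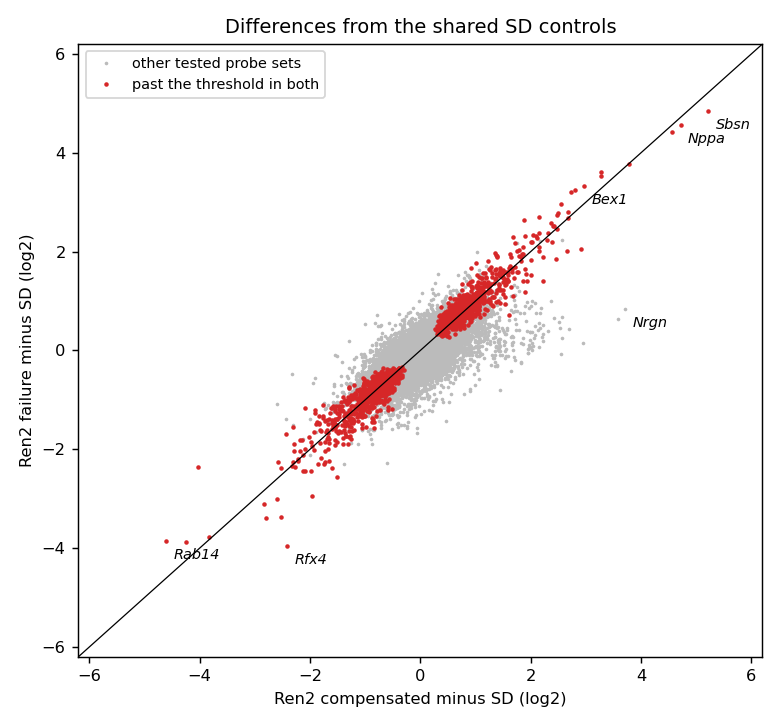
Log2 difference from the SD controls in failure rats (y axis) against that in compensated rats (x axis) for 18625 probe sets, with the line of equality; red points passed in both comparisons in the same direction. Sbsn (5.22 and 4.84) and Nppa (4.72 and 4.56) lie near the line, and Nrgn (3.72 and 0.84) lies below it.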

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

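The tests of the blood markers and of the fatty acid oxidation list, and that of strain sequence, were chosen after the result was seen; the test of RNA length for opposite probe sets and the counts over other splits were chosen before.

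Platelet and erythroid markers were lower in failure than in compensated rats, by −1.61 (95% interval −2.27 to −0.94) on the log2 scale for the mean of 13 markers. With the fluidics round as a block the difference was −1.61 (−2.41 to −0.82), which rests on round 2 alone. The levels there were 0.22 and 0.82 in compensated rats 5 and 6 and −1.55 and −0.64 in failure rats 7 and 8. The gap was thus present within 1 round. These rats, with rat 7 an outlier in the erythroid list, are too few to exclude a part of the round in it. The tables argue against loss of the RNA's 5' end as the whole cause, since the difference was −1.40 (−2.37 to −0.43) with the GAPDH ratio as a covariate. A difference in the blood left in the tissue, less in the failure group or more in the compensated group, stays open. Outside the pattern, S100a9 of neutrophils differed by −2.07 and Cpa3 of mast cells by −0.33. On average they differed by −1.20 (−1.95 to −0.45), and 2 genes are too few to decide. The mean of the 8 lymphocyte markers differed by −0.32 (exact permutation p = 0.0952, 0.407 after adjustment). A change in the animals' blood cells cannot be told apart from a difference in the blood left in the tissue. Against SD the platelet and erythroid medians were 1.49 and 1.95 in compensated rats and 0.08 and −0.10 in failure rats. The compensated group was thus the one that stood apart from the controls, whose arrays ran on another day.

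Fatty acid oxidation genes were lower in compensated rats than in SD controls, by −0.43 (95% interval −0.82 to −0.05) for the list's mean. Loss of the RNA's 5' end may account for it: within groups the list fell by 0.91 per unit of the log2 GAPDH ratio, and with the ratio as a covariate the difference was 0.21 (−0.31 to 0.74), an interval wide enough to hold both no change and a fall of 0.31. Run day and chip lot cannot be told apart from strain, because 0 run days held both. An effect of the Ren2 background stays open and untested.

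In 21 of 2487 genes with several tested probe sets, probe sets were called in opposite directions against the controls, among them Rab14 (−4.61 and 0.70), Hadha (−0.99 and 0.51), Eci1 (−0.68 and 1.23), Tpm1 (−1.06 and 0.46) and Vcl (−0.60 and 0.32) in compensated minus SD. The falling minus the rising probe sets differed by −1.46 ± 0.06 (SE) in compensated and −1.30 ± 0.06 in failure rats. With the GAPDH ratio as a covariate the compensated difference was −1.41 (−1.66 to −1.17). Within groups the falling minus the rising level moved by −0.07 per unit of the log2 ratio (−0.36 to 0.23). The genes were picked by their calls against SD on these same arrays, which fixes the sign of the difference and favours a small spread. The test therefore cannot decide on loss of the 5' end, which stays open. A difference in transcript sequence between the strains may account for the opposite calls and stays open. The Ren2 groups, which share a background, differed by 0.16 (0.03 to 0.29), but by 0.13 (−0.06 to 0.32) with the ratio as a covariate. Other splicing in the Ren2 ventricle stays open too, and so does run day, which cannot be told apart from strain.

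For the 1 Dgkd probe set of failure minus compensated (−1.90), chance cannot be excluded, as 13 of 100 splits of the 10 Ren2 rats gave as many and the highest other gave 109. That split set rats 1, 5, 7 and 9 apart. For its 12 list calls chance cannot be excluded either, as 10 of 100 splits called as many and the highest other called 17. These lists had median log2 differences of −0.37 (extracellular matrix), −0.0888 (sarcomere), −0.28 (immediate early genes), −0.17 (interferon), −0.30 (inflammatory cytokines), 0.16 (ubiquitin-proteasome), −0.59 (fibroblast), −0.21 (endothelial), −0.37 (macrophage), −0.28 (lymphocyte), −1.80 (erythroid) and −1.59 (platelet). Against the controls the counts of probe sets were beyond chance: only the real split, 1 of 100, gave 3667 in compensated minus SD (highest other 602), 1 of 35 gave 1985 in failure minus SD (highest other 2) and 1 of 100 gave 3511 for both Ren2 groups (highest other 2). The numbers of lists called there were not, since 37 of 100 splits called 9 or more (highest other 15) and 15 of 35 called 8 or more (highest other 14).

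Of 429 groups of 4 or 6 rats tested for a rat far from the others, 28 held one, where chance gives about 1 in 20, or 21.4. The gap to the nearest rat as a share of the group's range was above Dixon's 95% critical value in each. Failure rat 7 held 9 of them: Alas2 (0.881), Barhl2 (0.893), Bpgm (0.859), Rsad2 (0.989) and the erythroid list (0.928) were low, and Dgkd (0.874), Enah (0.889), Mcur1 (0.868) and the ribosome list (0.960) were high. Failure rat 9 was low in Gpx3 (0.953), the matrix list (0.901) and the fibroblast list (0.842), and failure rat 8 was high in the heat shock list (0.888). Compensated rat 5 was low in RT1-Db1 (0.638) and the renin-angiotensin list (0.657) and high in Rab14 (0.760) and the heat shock list (0.743). Single compensated rats stood low in Cryab (0.629, rat 6), Decr1 (0.656, rat 4) and Hsp90ab1 (0.706, rat 1), and high in Eno1 (0.921, rat 2), Rdx (0.714, rat 3) and the lymphocyte list (0.681, rat 4). Among the controls Agt was high in rat 14 (0.968) and RT1-Bb in rat 11 (0.839), while Gsn was low in rat 12 (0.919), Nfe2 in rat 11 (0.844) and the epicardium list in rat 13 (0.849).

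The poly-A spike-in probe sets, which entered no comparison, had signals above the highest control array in 5 Ren2 rats. As folds of the control mean they stood at 5.94 in failure rat 7, 3.93 in failure rat 9, 2.34 in compensated rat 2, 2.11 in compensated rat 5 and 1.89 in compensated rat 6.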

How the results depend on the processing

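Tests with modules or chip lots as blocks, within round 2, without failure rats 7 and 9, with poly-A signals or blood markers as covariates, and with the GAPDH ratio against SD were chosen after the data were seen. No paired analysis was possible because the groups share no rat numbers. Of 111 passing named genes 41 kept their call under every alternative and 70 lost it under at least 1; of 29 list calls only that of heat shock in failure minus SD was kept under all. The single count in failure minus compensated became 2 without a filter, 0 with the stricter filter, 0 with rounds as a block, 65 with modules, 0 within round 2 and 0 with the GAPDH ratio; leaving out 1 rat gave 1 to 84. Its 12 lists became 4 with rounds, 5 within round 2, 3 with blood markers, 4 without rats 7 and 9, 0 with an estimated correlation and 0 by fry, and 4 to 12 without 1 rat. With rounds as a random block (correlation −0.12) the counts were 6206 in compensated minus SD, 3636 in failure minus SD, 5954 for both groups and 2810 shared. A negative correlation shrinks the SE between rounds, and every SD array sat in round 4, so these higher counts do not show more changes. The GAPDH ratio gave 116, 687 for both groups and 110 shared, where the SE grew by a median of 1.85-fold in compensated minus SD. Blood markers gave 123, 1061 and 117. Failure minus SD had 1283 with modules, 1084 with poly-A signals and 710 without rats 7 and 9, and the shared count was 955, 930 and 647. Leaving out 1 rat gave 2561 to 3860, 1303 to 2239 and 2358 to 3532, with 1030 to 1629 shared. Lists against SD: 0 of 9 (compensated) and 1 of 8 (failure) with an estimated correlation, 5 by fry, 5 with poly-A signals and 5 without rats 7 and 9 in failure minus SD, and 8 to 11 and 7 to 9 without 1 rat. Median centring turned 1058 higher and 927 lower in failure minus SD into 780 and 872.

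Directions of results called in the main or the alternative fit turned as follows, for lists by camera's direction. With the GAPDH ratio the failure minus compensated medians were −0.24 for fatty acid oxidation (camera adjusted p = 1.77e-06), −0.19 for oxidative phosphorylation, −0.18 for the tricarboxylic acid cycle and −0.0339 for ubiquitin-proteasome, and in compensated minus SD 0.29 for fatty acid oxidation and 0.35 for the tricarboxylic acid cycle, with Rfx4 at 0.34 and Trim63 at 0.29. Quantile normalization gave 0.0413 for the sarcomere in failure minus compensated, −0.20 for oxidative phosphorylation and −0.17 for cardiomyocytes in compensated minus SD, and −0.0946 for oxidative phosphorylation in failure minus SD. Blood markers gave 0.26 for immediate early genes, −0.0458 for ubiquitin-proteasome and 0.18 for lymphocytes in failure minus compensated, and −0.41 for immediate early genes and 0.13 for Rfx4 in compensated minus SD. Within round 2 the fibroblast list was at −0.0024, with camera pointing up. Medians also changed sign where camera's direction did not. In failure minus compensated they were 0.0211 for interferon and 0.0461 for inflammatory genes with blood markers, 0.0060 for the sarcomere with median centring and 0.0120 for fibroblasts without rats 7 and 9. In compensated minus SD they were −0.0108 for glycolysis and −0.20 for the tricarboxylic acid cycle with quantile normalization and 0.18 for calcium handling with the GAPDH ratio, and −0.0868 for the tricarboxylic acid cycle in failure minus SD with quantile normalization. The cause was not tested, except that fewer arrays or added terms widen the SE. Dim probe sets, below a signal of 125, were left untested.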

Other observations

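The tests with blood markers as covariates and the exact permutation tests of list levels were chosen after the data were seen, and the genes mentioned were selected after their values were seen; the list tests were planned.

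Potassium channel genes differed from the SD controls in both directions. Kcnip2, a subunit of the channel that carries the transient outward current, rose by 0.84 ± 0.08 (SE) in compensated and 0.81 ± 0.09 in failure rats, while Kcnd3, a pore-forming subunit of the same channel, fell by 0.68 ± 0.13 in compensated rats and stood at −0.38 ± 0.14 in failure rats (limma adjusted p = 0.0938). Kcne1 rose in both. The list of 13 channel genes had 2 that rose and 1 that fell in each comparison, and adjusted over the list alone 2 rose and 1 fell in compensated and 2 rose and 2 fell in failure rats. Its median was −0.05 in compensated minus SD (camera adjusted p = 0.997), where its mean was 0.25 with Kcne1 at 3.27, and 0.12 in failure minus SD (0.833). Of the renin-angiotensin-aldosterone genes Nr3c2, the mineralocorticoid receptor, fell in both groups, by 0.61 ± 0.13 and 0.64 ± 0.14. Agt, angiotensinogen, rose by 1.28 ± 0.42 in compensated rats, a call that 17 alternatives ended. The 6 genes of this list had medians of −0.00405 and −0.07 against SD, with 1 that rose and 1 that fell in compensated and 1 that fell in failure rats, adjusted over the list alone as well.

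Of 7 atrial genes 3 rose in compensated rats, adjusted over the list alone as well (median 0.52, camera adjusted p = 0.00561, adjusted p = 0.183 with an estimated correlation), among them Nppa, the atrial myosin light chain Myl7 (2.56 ± 0.66, SE) and Pam, which amidates peptides (0.80 ± 0.10). In failure rats 2 rose, or 3 adjusted over the list alone (median 0.49, camera adjusted p = 0.0119, adjusted p = 0.338 with an estimated correlation), with Pam at 0.72 ± 0.10 and Myl7 at 2.23 ± 0.72 (limma adjusted p = 0.0577). Without the filter on dim probe sets neither call held, with medians of 0.34 (camera adjusted p = 0.166) and 0.28 (0.290). Nppa is also in the hypertrophy list. Of 24 oxidative stress genes 6 rose and 1 fell in compensated rats, adjusted over the list alone as well (median 0.22, camera adjusted p = 0.0245, adjusted p = 0.183 with an estimated correlation, 0.0978 without SD rat 14). Ucp2, a mitochondrial carrier, rose by 1.36 ± 0.19, Sod3, the extracellular superoxide dismutase, by 1.61 ± 0.34 and Gpx3, a secreted glutathione peroxidase, by 1.29 ± 0.31, while the call of the list was lost with blood markers as covariates (median 0.23, camera adjusted p = 0.148) and with quantile normalization (0.20, 0.0663), though its median hardly moved. In failure rats 2 rose and 1 fell, or 4 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 0.247). By the exact permutation test of list levels, 4 lists of compensated minus SD passed after adjustment over 35 lists: atrium (1.32), hypertrophy (0.84), heat shock (0.43) and oxidative stress (0.33), each with exact p = 0.00476, the smallest possible, and adjusted p = 0.0417. In failure minus SD 7 lists reached the smallest exact p, 0.0286, which became 0.143 after adjustment, so none passed. With 4 against 4 rats there are 70 groupings, and a list at the smallest p passes only if many others share it. The differences there were 1.17 for atrium, 0.83 for hypertrophy, 0.45 for heat shock and 0.14 for oxidative stress. The lack of calls therefore does not by itself mark smaller shifts than in compensated rats.

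Camera made no call for the lists and comparisons that follow. Fry called 10 lists in compensated minus SD, where camera called 9, and it did not call fatty acid oxidation (fry adjusted p = 0.174). Some lists without a camera call in that comparison were therefore called by fry. In failure minus compensated the medians were −0.02 for hypertrophy, 0.20 for fatty acid oxidation (camera adjusted p = 0.058), 0.08 for glycolysis, 0.0063 for heat shock, −0.04 for channels, −0.21 for renin-angiotensin, −0.16 for atrium and −0.10 for oxidative stress. In the order failure minus compensated, compensated minus SD and failure minus SD, the medians were 0.03, 0.0018 and 0.05 for oxidative phosphorylation, 0.0029, 0.0087 and 0.07 for the tricarboxylic acid cycle, 0.06, −0.00042 and 0.12 for calcium handling, and −0.10, 0.27 and 0.17 for the lysosome. They were −0.03, 0.07 and 0.03 for endoplasmic reticulum stress, −0.09, 0.15 and 0.00036 for the cell cycle, and −0.02, 0.05 and 0.03 for the cytosolic ribosome. For cell types they were −0.03, 0.11 and 0.13 for cardiomyocytes, −0.09, 0.12 and −0.22 for smooth muscle and pericytes, −0.11, 0.04 and −0.22 for adipocytes, and −0.18, 0.06 and 0.04 for epicardium. They were −0.13, 0.26 and 0.32 for skeletal muscle, −0.27, 0.07 and −0.24 for Schwann cells and neurons, 0.05, 0.26 and 0.19 for lung, and −1.20, 0.91 and −0.29 for the 2 neutrophil and mast cell genes, which were not tested as a list. Against SD, ubiquitin-proteasome genes had medians of −0.13, with 4 of 16 that fell in compensated rats, adjusted over the list alone as well, Psma5 (−0.44 ± 0.10, SE) and Trim63 (−0.73 ± 0.24) among them, and −0.07 in failure rats. The Trim63 call was ended by 17 alternatives, and with the GAPDH ratio as a covariate it stood at 0.29. The intercalated disc stood at −0.02 and 0.10, macrophages at 0.32 and −0.06, endothelium at 0.15 and −0.15, lymphocytes at 0.24 and −0.15, inflammatory cytokines at 0.12 and −0.02, immediate early genes at 0.01 and −0.13, and in compensated rats fibroblasts at −0.29 and interferon genes at −0.12.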
